A study of Mus musculus with 16 samples.

How the data were processed

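RNA was measured from mouse hypothalamus with bacTRAP, in which ribosomes carrying the large-subunit protein L10a fused to GFP are precipitated with anti-GFP antibodies from the cells that express Cre recombinase. Per the labels' protocols, Cre was driven by Pnoc, the gene of the neuropeptide precursor prepronociceptin, and the tissue of 4 animals was pooled for each sample. A lysate aliquot taken before the precipitation gave the input library of a pool and the ribosome-bound RNA gave its pulldown library. The 16 libraries formed 4 groups of 4, namely input and pulldown of control pools 1 to 4 and of pools 5 to 8 with Lepr deleted in Pnoc-expressing cells. Animals were 12 weeks old per the treatment protocol and 10 to 12 weeks old per the extraction protocol, on a C57Bl/6N background, chow-fed and sampled in the random-fed state. Pools are separate sets of animals, so the spread between libraries of a group includes variation between pools but not between single animals.

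Per the submitters' processing notes, the tools were Salmon 1.10.1 and DESeq2 1.38.3 and the genome build was GRCm38. Read trimming, the annotation release and the strand setting were not given in the sources used here, so overlapping, antisense and near-identical genes were treated as uncertain. The authors deposited estimated counts per gene, which need not be whole and are summed over a gene's transcripts. The authors also deposited TPM per gene, and estimated counts rescaled from TPM to each library's total, which divides out gene length. A further deposited table held the authors' log2 fold changes and adjusted p-values for 4 comparisons, whose design formula and filters were not given in the sources used here. Each count table had 45706 gene rows, of which 33642 were matched by symbol or synonym to a position in the GRCm38.p6 annotation. A gene-level total cannot show which part of a floxed gene was removed.

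Estimated counts were rounded to whole numbers and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3), TMM scaling and Benjamini-Hochberg adjustment at 0.05, on genes kept by filterByExpr (minimum count 10, minimum total 15). Tests are two-sided. Each of the 4 comparisons of a pair of groups used the 8 libraries of those groups, and the 16 libraries together gave the difference of enrichment between genotypes. Levels are TMM-scaled CPM over the 16 libraries, and fold changes are log2 values with standard errors (SE). Library totals were 64435952 to 78623636 counts, so that 3 counts, taken as the floor, correspond to 0.0469 to 0.0562 TMM-scaled CPM in input and 0.0321 to 0.0396 in pulldown. Reads carried no molecular identifiers in the tables used, so floors and counting intervals cover counting error only. Replicate libraries differed by far more than counting noise, with a chi-square per degree of freedom of 8.16 to 49.9 over the 24 within-group pairs.

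Before the data were examined, 32 gene lists were fixed. They covered the targets, leptin-STAT3 signalling, feeding peptides, AgRP and POMC neuron markers, GABAergic, glutamatergic and pan-neuronal genes. They also covered markers of astrocytes, oligodendrocytes, oligodendrocyte precursors, microglia, vascular cells, tanycytes and ependyma, choroid plexus with blood and pituitary, and neighbouring brain regions. The others were hypothalamic transcription factors, immediate early genes, ER stress, heat shock, mitochondrially encoded genes, nuclear oxidative phosphorylation genes, ribosomal proteins, metabolic receptors, GABA receptors, glutamate receptors, ion channels, circadian, sex-linked, cholesterol synthesis, interferon and peptide-processing genes. Lists were tested with limma's camera (limma 3.58.1) with a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the 32 lists. Exact permutation tests of 4 against 4 libraries have 70 assignments and a smallest two-sided p of 0.0286.

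The rule for genes named in the text was also fixed before the data were examined. It took Lepr, Leprot, Pnoc and Rpl10a, and, among passing genes with ordinary symbols and no overlap between groups, the 12 largest changes in each direction at a mean log2 CPM of at least 2 and the 5 smallest p in each direction. It added up to 4 members of each list with the smallest p. Genes named outside this rule are said to be so.

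Input and pulldown libraries of one number came from one lysate per the extraction protocol. Deviations from the group means correlated between same-numbered libraries with values of 0.08 to 0.57, above 0.1 in 6 of 8 pairs, and in 6 of 8 pairs the own number gave the best match. The fits did not include the pool as a block, which was run as an alternative. Other alternatives were RLE factors, scaling by library totals, no filter, a minimum mean of 1 CPM, DESeq2 1.42.0, the rescaled counts, limma on log2(TPM + 1) and log2(TPM + 0.1), and removal of mitochondrially encoded genes. Further alternatives were all 16 libraries in one fit, a glial covariate, a test against a 2-fold change, an adjusted p of 0.1 and each library left out in turn. Fits with newer edgeR dispersions, with a Y-linked covariate, with DESeq2 on all 16 libraries and without pools 1 and 5 were chosen after seeing the data.

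The tests were tried on simulated counts drawn from the real means, library sizes and dispersions with 200 changed genes and a list of 20 more changed 1.5-fold. For Lepr deletion against control in pulldown, simulated on 16859 genes, edgeR recovered 34% of genes changed 1.25-fold, 70% at 1.5-fold, 86% at 2-fold and 96% at 4-fold, and 11 of the 20 listed genes, with 13 false among 167 calls. For the same comparison in input, on 17735 genes, it recovered 38%, 64%, 66% and 96%, and for the difference of enrichment, on 18530 genes, 10%, 44%, 66% and 92%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.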

Results

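The series profiled hypothalamic RNA bound to ribosomes of PNOC neurons, cells that express prepronociceptin, in control mice and in mice with the leptin receptor gene Lepr deleted in those neurons. Each of 8 pools of 4 animals, 4 control pools and 4 Lepr-deletion pools, gave an input library of total hypothalamic RNA and a pulldown library of precipitated ribosomes. Estimated counts summed to 65218805 to 74726368 in control input libraries and 65066280 to 72519389 in Lepr-deletion input libraries. They summed to 73039384 to 78036810 in control pulldown and 64435952 to 78623636 in Lepr-deletion pulldown. Between 22765 and 23345 genes had counts in an input library and between 21324 and 21790 in a pulldown library. Mitochondrial ribosomal RNA made up 27.3% ± 0.583 (SD, n = 4) of control input, 24.5% ± 0.973 of Lepr-deletion input, 0.0752% ± 0.0103 of control pulldown and 0.0649% ± 0.00236 of Lepr-deletion pulldown.

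The targeted gene was not lower in the libraries labelled Lepr deletion. Lepr (ENSMUSG00000057722, GRCm38 chromosome 4, 101717137 to 101815352), which encodes the receptor of the fat-derived hormone leptin, had 1.86, 1.42, 1.65 and 1.55 CPM in the pulldown of control pools 1 to 4. It had 2.42, 2.54, 2.82 and 2.68 CPM in the pulldown of pools 5 to 8. In input it had 4.54, 5.11, 3.49 and 4.02 CPM in control pools 1 to 4 and 5.95, 5.27, 8.14 and 4.78 CPM in pools 5 to 8. Between 133 and 162 counts lay behind each control pulldown value and between 203 and 243 behind each Lepr-deletion pulldown value. These totals cover all isoforms of the gene, and which part was deleted was not given in the sources used here, so they check nothing about the labels. Leprot, which lies next to Lepr on chromosome 4 (101647783 to 101659364), had 7.57 ± 0.237 CPM (SD, n = 4) in control pulldown and 7.7 ± 0.998 CPM in Lepr-deletion pulldown.

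**Figure D1:**
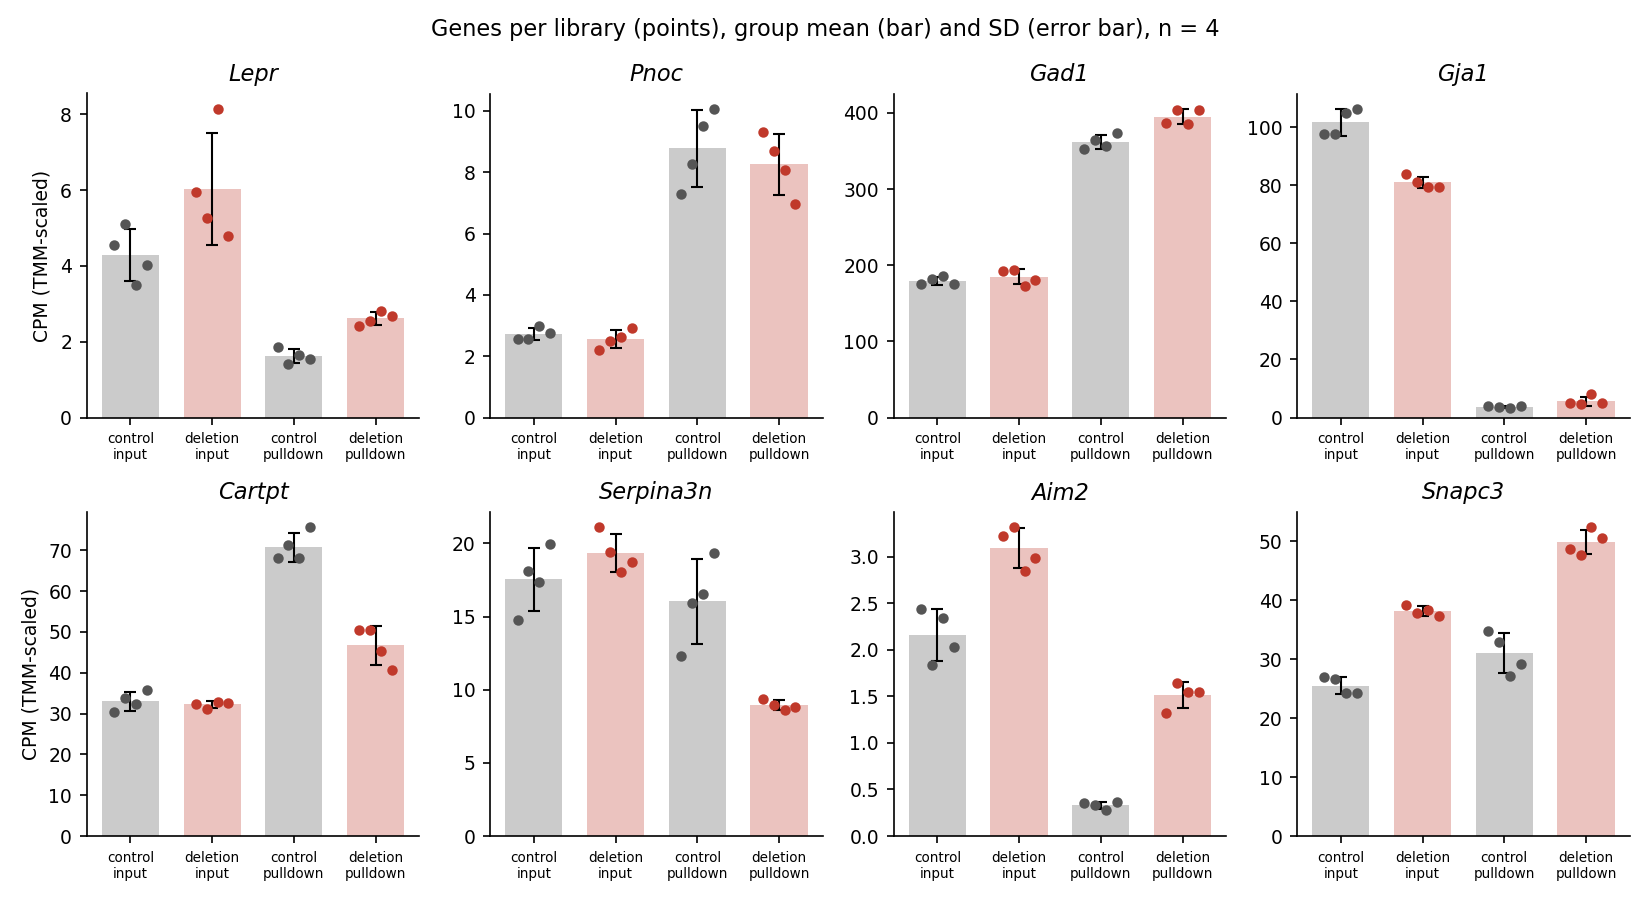
TMM-scaled CPM of 8 genes in each of the 16 libraries (points), with group means (bars) and SD (error bars, n = 4), grey for control and red for libraries labelled Lepr deletion. Pnoc and Gad1 were higher in pulldown than in input in both genotypes and Gja1 was lower, and Cartpt and Serpina3n were lower in Lepr-deletion than in control pulldown.

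The first question was which RNAs the precipitated ribosomes of control PNOC neurons carried relative to the whole hypothalamus. Pnoc itself (chromosome 14, 65400673 to 65425564) was 8.78 ± 1.25 CPM in pulldown and 2.71 ± 0.196 CPM in input (SD, n = 4 each), a log2 fold change of 1.68 (SE 0.12). Transcripts of other hypothalamic peptides were higher too. Ghrh, growth hormone-releasing hormone, was higher by 2.40 on the log2 scale, Sst, somatostatin, by 2.13 and Trh, thyrotropin-releasing hormone, by 1.63. Nts, neurotensin, was higher by 1.43 and Cartpt, the CART peptide precursor, by 1.08. Gad1, which makes the inhibitory transmitter GABA, rose by 1.00, and Dlx1, a transcription factor of GABAergic neurons, by 1.09. Lepr was lower in pulldown, at -1.42, and Rpl10a, the gene whose protein was tagged, was higher, at 0.25. Leprot was lower by the TMM-scaled test, at -0.34, but at 0.21 when counts were scaled by library totals and at 0.60 when tested as log2(TPM + 1). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 11381 of 17570 genes passed, 5297 higher and 6084 lower, and 248 and 3249 of them by more than 2-fold. Scaling by library totals called 14044 genes with 76.2% of them higher, against 46.5% with TMM, and limma on log2(TPM + 1) called 12867 with 90.7% higher. Those scalings moved the median of all genes by 0.546 and 0.928, so directions are given relative to TMM scaling, and where they turn under another scaling this is said.

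Pan-neuronal and GABAergic genes were higher in control pulldown, while glutamatergic genes went both ways. Of 20 pan-neuronal genes 17 were higher and 2 lower, with Ndrg4 at 0.91 and Rbfox3, the neuronal nuclear antigen NeuN, at 0.66 (camera adjusted p = 9.29e-05, and adjusted p = 0.0637 with an estimated correlation). Of 16 GABAergic genes 12 were higher and 2 lower (adjusted p = 0.000981, and adjusted p = 0.286 with an estimated correlation). AgRP neuron markers were higher in 8 and lower in 1 of 12, with Asb4 at 0.62 and Otp at 0.79 (adjusted p = 0.0373, and adjusted p = 0.351 with an estimated correlation). Agrp itself (named outside the rule) was not higher, with mean log2 CPM of 1.7 in pulldown and 1.85 in input (exact permutation test, p = 0.543). Peptide-processing genes were higher in 12 and lower in 2 of 18, among them the convertase gene Pcsk2 at 0.61 and the vesicle-release gene Cadps at 0.64 (adjusted p = 0.0373, and adjusted p = 0.636 with an estimated correlation). GABA receptor genes were higher in 10 of 17 and lower in 0, with Gabra5 at 0.46 (adjusted p = 0.0266, and adjusted p = 0.546 with an estimated correlation). Feeding peptides went both ways, with 17 higher and 11 lower of 34 (adjusted p = 0.164). So did POMC neuron markers, with 7 higher and 3 lower of 13 (adjusted p = 0.252). Hypothalamic transcription factors had 14 higher, including Foxb1 at 1.65 and Isl1 at 0.60, and 7 lower, including Nr5a1 at -1.87, of 28 (adjusted p = 0.137).

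Markers of other cell types were lower in control pulldown, under library totals and TPM scaling as well. All 16 astrocyte genes were lower, with the gap junction gene Gja1 at -4.78, the water channel gene Aqp4 at -4.85 and Slc1a3, a glutamate transporter gene, at -4.61 (camera adjusted p = 5e-11, and adjusted p = 0.0458 with an estimated correlation). All 10 oligodendrocyte precursor genes and all 15 microglial genes were lower, with Olig1 at -4.16 and the purinergic receptor gene P2ry12 at -5.03 (adjusted p = 2.09e-06 and 2.81e-07, and adjusted p = 0.0458 for each with an estimated correlation). All 15 oligodendrocyte genes were lower, with Ermn at -4.81 and the myelin gene Cnp at -3.04 (adjusted p = 3.46e-09, and adjusted p = 0.226 with an estimated correlation). Tanycyte and ependymal genes were lower in all 14, with the deiodinase gene Dio2 at -3.42 (adjusted p = 2.09e-06, and adjusted p = 0.0648 with an estimated correlation). Vascular genes were lower in 12 and higher in 1 of 14, with the pericyte gene Rgs5 at -3.85 (adjusted p = 0.00195, and adjusted p = 0.133 with an estimated correlation). Choroid plexus, blood and pituitary genes were lower in 9 of 11, with the haemoglobin gene Hbb-bs at -4.68 (adjusted p = 0.00081, and adjusted p = 0.226 with an estimated correlation).

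RNAs from different compartments separated as well. All 13 mitochondrially encoded mRNAs were lower in control pulldown, with mt-Nd4 at -8.58 and mt-Atp8 at -9.05 (adjusted p = 1.63e-09, and adjusted p = 0.174 with an estimated correlation), and the ribosomal RNAs mt-Rnr1 and mt-Rnr2 were at -8.53 and -9.70. Nuclear genes of oxidative phosphorylation were higher in 30 of 31, with Cox6a1 and Cycs, cytochrome c, at 0.67 each (adjusted p = 8.47e-11, and adjusted p = 0.136 with an estimated correlation). Ribosomal protein genes were higher in 42 and lower in 3 of 61, with Rpl15 at 0.50 (adjusted p = 1.79e-05, and adjusted p = 0.546 with an estimated correlation). Heat shock genes were higher in 8 and lower in 1 of 14 (adjusted p = 0.0276, and adjusted p = 0.546 with an estimated correlation). The long noncoding RNAs Meg3 and Snhg11, the 2 pan-neuronal genes that were lower, were at -4.82 and -3.90 and Xist at -3.19, while Snhg3 was higher by 2.28, and such RNAs were not tested as a list. Interferon genes were lower in all 18, with Ifitm3 at -3.71 (adjusted p = 7.08e-05, and adjusted p = 0.349 with an estimated correlation). Gbp7, a member of the leptin-STAT3 list, was at -2.62. Cholesterol synthesis genes were lower in 16 of 19 with TMM, including Lss at -1.07 but their median of -0.53 turned to 0.02 with library totals and 0.40 with TPM (adjusted p = 0.000591, and adjusted p = 0.367 with an estimated correlation). It lay -0.51, -0.51 and -0.53 from the median of all genes.

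The other lists did not pass the set test in control. Leptin-STAT3 genes were higher in 3 and lower in 14 of 23 (adjusted p = 0.103), glutamatergic genes 6 and 8 of 15 (0.838), neighbouring-region genes 2 and 7 of 14, with the striatal gene Ppp1r1b at -3.00 (0.164), and circadian genes 4 and 6 of 18 (0.842). Metabolic receptors were higher in 12 and lower in 10 of 37 (0.795), and sex-linked genes lower in 3 of 6 (0.145). The medians of these 6 lists turned positive with TPM, and those of 5 of them, all but the sex-linked genes, with library totals. Ion channels, with Kcnj3 at 0.72 and Kcnj9 at 0.78, were higher in 18 and lower in 6 of 47 (0.0581), glutamate receptors, with Grin2c at -3.90, 6 and 4 of 22 (0.334), immediate early genes 5 and 4 of 22 (0.301), ER stress genes 7 and 3 of 20 (0.252) and the targets 2 and 2 of 4, with a median of -0.04 that turned to 0.50 with library totals and 0.93 with TPM (0.765).

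**Figure D2:**
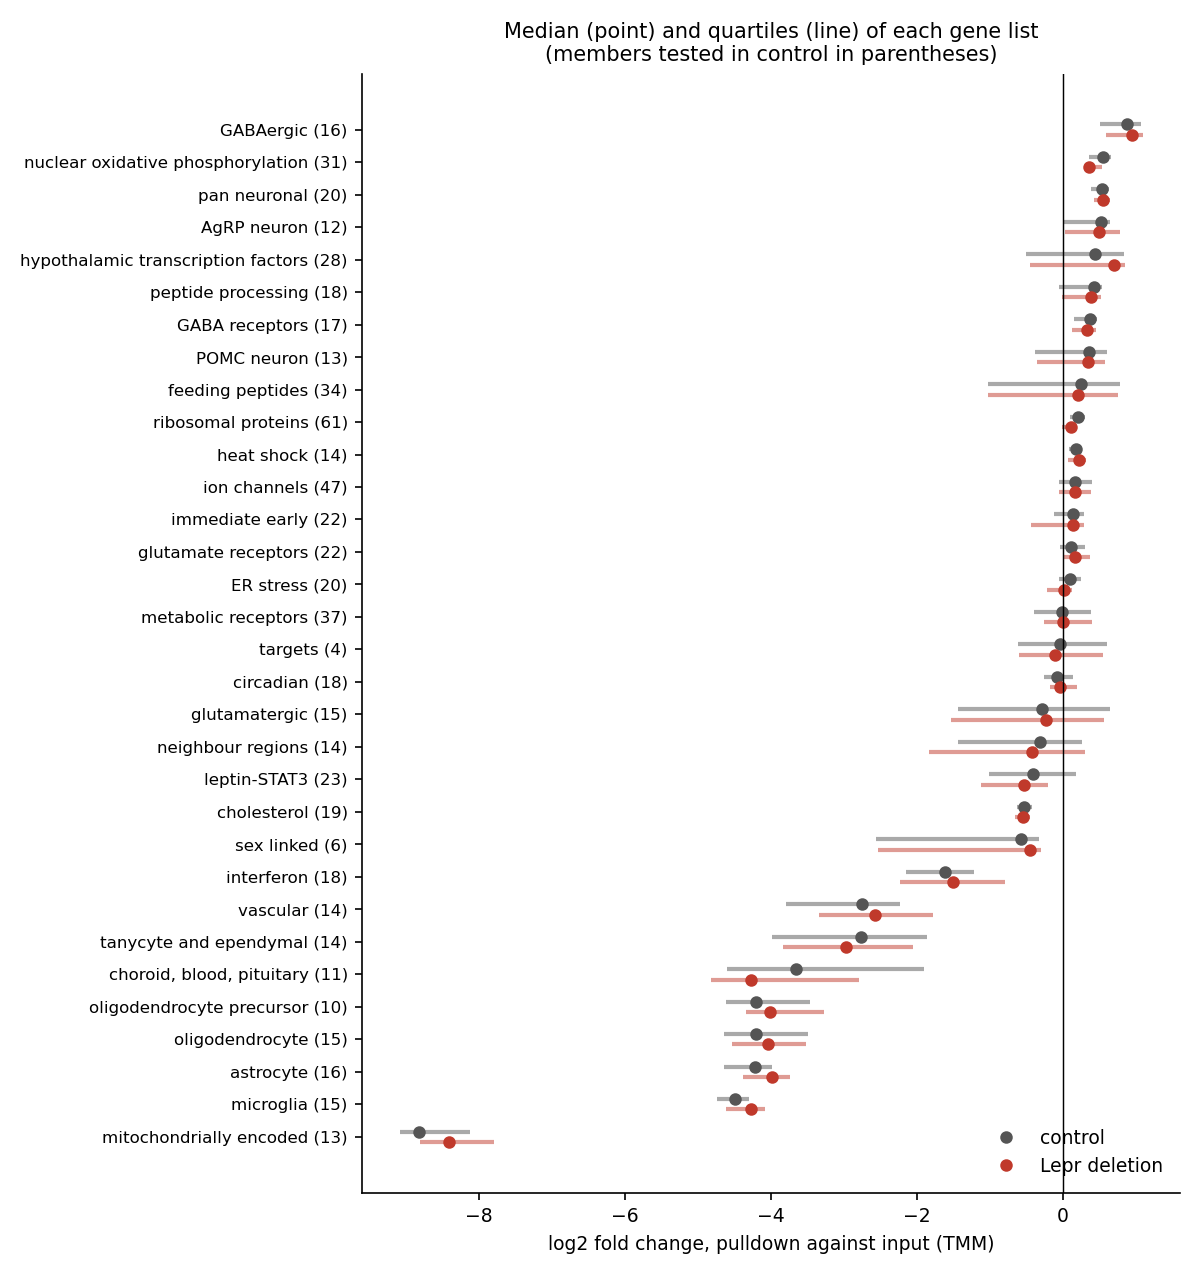
Median (points) and quartiles (lines) of the log2 fold change of pulldown against input over the tested members of each of 32 gene lists, grey for control and red for Lepr deletion, with TMM scaling. Astrocyte, oligodendrocyte and microglial lists had medians of -4.22, -4.21 and -4.49 in control and mitochondrially encoded genes -8.83, while the cholesterol median of -0.53 turned to 0.40 with TPM.

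In Lepr-deletion pools the same question gave a similar order of genes. Pnoc was 8.25 ± 0.998 CPM in pulldown and 2.56 ± 0.293 CPM in input (SD, n = 4 each), a log2 fold change of 1.68 (SE 0.12). Ghrh was higher by 2.35, Sst by 2.12, Crabp1, a retinoic acid-binding protein gene, by 2.00, Onecut3 by 1.56, Gad1 by 1.08 and Npy, neuropeptide Y, by 0.99. Avp, vasopressin, was at -4.66, Pomc, the melanocortin precursor gene, at -1.55, the astrocyte genes Slc1a2 and S100b at -3.84 and -4.03, and Tyrobp of microglia at -5.01. Lepr was at -1.22, and Leprot was at -0.39 with TMM but at 0.07 with library totals and 0.45 as log2(TPM + 1). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 10740 of 17423 genes passed, 5026 higher and 5714 lower, against 74.4% higher among 13438 with library totals and 89.7% higher among 12779 with limma on log2(TPM + 1). All 16 astrocyte, 15 oligodendrocyte, 15 microglial and 13 mitochondrially encoded genes were lower (adjusted p with an estimated correlation 0.101, 0.147, 0.101 and 0.101), and 17 of 20 pan-neuronal and 12 of 16 GABAergic genes were higher (adjusted p with an estimated correlation 0.101 and 0.147). The genotypes shared 4366 of the genes higher in pulldown, where 1550 would be shared by independent lists, and 4991 of those lower, where 1910 would be. Another 3 genes passed in opposite directions, and log2 fold changes correlated across genes with r = 0.956, although genes are not independent replicates.

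The next comparison asked which ribosome-bound RNAs differed between libraries labelled Lepr deletion and control. Cartpt, whose peptide reduces feeding, was lower, at 46.8 ± 4.73 CPM against 70.7 ± 3.56 CPM (SD, n = 4 each, log2 fold change -0.58, SE 0.07, adjusted p = 0.00399 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Serpina3n, a serine protease inhibitor gene, was lower, at 8.95 ± 0.318 against 16 ± 2.88 CPM (-0.83, SE 0.12, adjusted p = 0.0103). Acer2, an alkaline ceramidase gene, was lower, at 2.19 ± 0.269 against 6.57 ± 0.564 CPM (-1.57), and Aim2, a cytosolic DNA sensor gene, was higher, at 1.51 ± 0.135 against 0.331 ± 0.0392 CPM (2.20). Snapc3, of a small nuclear RNA transcription complex, was higher by 0.70, a value left uncertain by its overlap with Psip1 (0.28). Efcab7 was at -0.85, Erdr1 at -0.97, Dner, a neuronal Notch ligand gene, at -0.64 and Mal2 at -0.41. Lepr was higher by 0.71 (SE 0.12, adjusted p = 0.0386), and Pnoc, Leprot and Rpl10a did not pass, at -0.08, 0.04 and -0.11. Npy, which promotes feeding, was 27.8 ± 1.89 against 21 ± 3.09 CPM and did not pass (0.42, adjusted p = 0.0671). Nor did Gal, galanin (-0.45, 0.0636), Cck, cholecystokinin (-0.48, 0.0948), or Pomc (-0.34, 0.0964). Of 16859 genes 108 passed, 66 higher and 42 lower, with 14 and 1 over 2-fold and a median size of 0.375 on the log2 scale. With library totals 76 passed, of which 39.5% were higher, against 61.1% with TMM.

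Those calls depended on single libraries. Without the pulldown library of pool 6, 7 or 8, 19, 19 and 25 genes passed, without that of pool 2, 3 or 4, 21, 30 and 29, and without that of pool 1 or 5, 556 and 1262. Acer2, Aim2, Cartpt, Chka, Dner, Efcab7, Erdr1, Mal2, Snapc3 and Zscan26 passed in all 8 of these fits, with Cartpt between -0.64 and -0.54. Lepr did not pass without pool 6, 7, 8, 2, 3 or 4 (adjusted p = 0.144, 0.184, 0.113, 0.155, 0.115 and 0.094), nor with rescaled counts (0.34, adjusted p = 0.504) or limma on log2(TPM + 1) (0.21, adjusted p = 0.417). Serpina3n did not pass without pool 6, 7, 8 or 2 (adjusted p = 0.0724, 0.0693, 0.0606 and 0.0539), and Aim2 did not pass with rescaled counts (adjusted p = 0.0997).

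Heat shock genes were higher in Lepr-deletion pulldown. Among 14 tested, Dnajb1 and Hsph1, a co-chaperone and a chaperone gene, rose by 0.34 and 0.27, 10 rose when adjusted over the list alone, and all 14 had positive values, among them Hspa1b at 0.73 and Hspd1 at 0.24 (camera adjusted p = 2.65e-06, and adjusted p = 0.676 with an estimated correlation). Ion channel genes had negative values in 40 of 47, with only Kcnj3, an inward rectifier channel gene, passing over all genes tested (-0.30), and 3 fell when adjusted over the list alone (adjusted p = 7.45e-05, and adjusted p = 0.676 with an estimated correlation). Glutamate receptor genes had negative values in 21 of 22, with Grm4 at -0.39, peptide-processing genes in 15 of 18, with Nucb2 at -0.31 and Pam at -0.21, and GABA receptor genes in 12 of 17, with Gabra4 at -0.28. No member of these 3 lists passed edgeR's test over all genes, where 3340 genes had an unadjusted p under 0.05 and DESeq2 called 1052. Of them 4, 5 and 5 fell, and 2 peptide-processing genes rose, when adjusted over the list alone (camera adjusted p = 0.00478, 0.00478 and 0.0458, and adjusted p = 0.676 for each with an estimated correlation). The 4 lists of channel, receptor and peptide-processing genes had means of 5.60 log2 CPM in control pool 1 and 5.82 to 5.96 in control pools 2 to 4, and of 5.81 in pool 5 and 5.58 to 5.63 in pools 6 to 8. Pool 1 thus lay among pools 6 to 8, and pool 5 lay just below control pools 2 to 4. In pulldown, Y-linked genes had a mean of 3.00 log2 CPM in control pool 1 against 3.77 to 3.98 in pools 2 to 4, and of 3.62 in pool 5, 3.66 to 4.00 in pools 6 and 7 and 4.78 in pool 8, and 29 genes passed with this mean as a covariate, added after seeing the data. Without pools 1 and 5, a choice made after seeing the data, 3363 genes passed, and 32 of 47 ion channel, 17 of 22 glutamate receptor, 10 of 17 GABA receptor and 15 of 18 peptide-processing genes fell.

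Other groups changed in few members. Feeding peptides had Cartpt as the only member passing of 34, with 1 higher and 5 lower when adjusted over the list alone (camera adjusted p = 0.0063, and adjusted p = 0.676 with an estimated correlation). Among 22 immediate early genes, Nr4a3 rose by 0.57 and Npas4 and Btg2 fell, at -0.83 and -0.63 (adjusted p = 0.265), and these 3 calls were lost without the pulldown library of pool 2, 3, 4, 6, 7 or 8. Among 22 leptin-STAT3 genes, Serpina3n fell and Stat3, the transcription factor downstream of the receptor, was at -0.10 (adjusted p = 0.155). Interferon genes had positive values in 17 of 18 (adjusted p = 0.00478) and astrocyte genes in 14 of 16, with Gja1 at 0.60 (adjusted p = 0.0458), and no member passed in either (adjusted p = 0.676 for both with an estimated correlation). Ribosomal protein genes had negative values in 51 of 61 and none passed (adjusted p = 0.00825, and adjusted p = 0.769 with an estimated correlation). Vascular genes had positive values in 9 of 11, with Vtn at 1.72 and Flt1 at 1.60 (adjusted p = 0.111).

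The same contrast in input asked which of these differences were present in the whole hypothalamus. The largest change by p was in mt-Nd3, a mitochondrially encoded subunit of respiratory complex I, with a log2 fold change of 1.65 (SE 0.07, adjusted p = 2.01e-08 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Its value is uncertain because reads can be shared with a near-identical nuclear copy, Gm28438 (named after its values were seen), which was at -5.13. Other mitochondrially encoded RNAs were lower, with mt-Atp6 at -0.32, mt-Rnr2 at -0.24 and mt-Rnr1 at -0.20. Snapc3 rose by 0.58, Atp6v1g1 of the proton pump by 0.48, the small nuclear RNA Rn7sk by 0.53, Fosl2 by 0.47, Dnajb1 by 0.45 and Adss, of adenine nucleotide synthesis, by 0.37. Acer2 was at -0.91, Efcab7 at -0.98, Synpr, of synaptic vesicles, at -0.57, Wdfy1 at -0.55, Mt2, a metallothionein gene, at -0.43 and Gja1 at -0.33. Cartpt was at -0.04 in input with TMM and at 0.03 with library totals, and it did not pass (adjusted p = 0.84). Serpina3n (0.14, adjusted p = 0.503), Aim2 (0.52, adjusted p = 0.169) and Lepr (0.49, adjusted p = 0.229) did not pass in input. Nor did Pnoc (-0.08, and 0.01 with TPM), Leprot (0.08) or Rpl10a (-0.03, and 0.04 with library totals). Of 17735 genes 41 passed, 24 higher and 17 lower. With library totals 108 passed, of which 87% were higher, against 58.5% with TMM.

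Without the input library of pool 6, 7, 2 or 3, 22, 24, 24 and 19 genes passed, and without that of pool 5 or 1, 337 and 402. The calls of mt-Nd3, mt-Atp6, Snapc3, Atp6v1g1, Rn7sk, Fosl2, Adss, Acer2, Wdfy1 and Gja1 held in all 8 of these fits. Those of Efcab7 were lost without pool 7, 8, 2 or 3 (adjusted p = 0.0505, 0.0566, 0.0502 and 0.0793). Those of Synpr were lost without pool 6, 7 or 3 (0.0863, 0.0567 and 0.0699), and of Dnajb1 without pool 3 (0.0699). That of Mt2 was lost without pool 6, 7, 3 or 4 (0.157, 0.074, 0.12 and 0.0705), that of mt-Rnr1 without pool 6, 7, 8, 2 or 3 and that of mt-Rnr2 without any of pools 2, 3, 4, 6, 7 and 8.

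Among gene groups in input, heat shock genes had positive values in all 14 with 10 higher when adjusted over the list alone (camera adjusted p = 6.07e-07, and adjusted p = 0.734 with an estimated correlation). Of 13 mitochondrially encoded mRNAs, mt-Nd3 rose and mt-Atp6 fell over all genes, and 11 fell when adjusted over the list alone (adjusted p = 1.94e-05, and adjusted p = 0.734 with an estimated correlation). Ion channel genes had negative values in 41 of 47, with Kcnj3 at -0.33, and glutamate receptor genes in 22 of 22 (adjusted p = 6.58e-08 and 1.58e-06, and adjusted p = 0.734 for both with an estimated correlation). GABA receptor genes had negative values in 16 of 17, peptide-processing genes in 15 of 18 and metabolic receptor genes in 29 of 37 (adjusted p = 0.00206, 0.00213 and 0.0489, and adjusted p = 0.734, 0.734 and 0.928 with an estimated correlation). Vascular genes had positive values in 13 of 14 and tanycyte and ependymal genes in 12 of 14 (adjusted p = 0.00206 and 0.0171, and adjusted p = 0.734 for both with an estimated correlation). Nuclear oxidative phosphorylation genes had positive values in 28 of 31, ribosomal protein genes in 44 of 61 and leptin-STAT3 genes in 16 of 22 (adjusted p = 0.000475, 0.00277 and 0.0332, and adjusted p = 0.734, 0.928 and 0.734 with an estimated correlation). Astrocyte genes had a negative median of -0.08, which turned to 0.01 with TPM, and 2 of 16 fell (adjusted p = 0.0324, and adjusted p = 0.734 with an estimated correlation). The means of the channel, receptor and peptide-processing lists were 5.01 log2 CPM in control pool 1 against 5.22 to 5.29 in pools 2 to 4, and 5.19 in pool 5 against 4.96 to 4.99 in pools 6 to 8. Those of Y-linked genes in input were 3.26 in control pool 1 against 4.08 to 4.33 in pools 2 to 4, and 4.10 in pool 5, 3.83 to 4.23 in pools 6 and 7 and 4.92 in pool 8, and 246 genes passed with this covariate. Xist, also sex-linked, went the other way at these extremes, highest in pool 1 (2.81 log2 CPM) and lowest in pool 8 (1.25). The sex composition of the pools was not tested. Without pools 1 and 5, chosen after seeing the data, 1957 genes passed, and 30 of 47 ion channel and 16 of 22 glutamate receptor genes fell.

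Of the 108 genes passing in pulldown, 107 were tested in input, 100 had the same sign there and 20 passed. The fractions shared 15 of the genes higher in Lepr deletion, where 0.0954 would be shared by independent lists, and 5 of those lower, where 0.0411 would be. Input and pulldown came from the same lysates, so the fractions are not independent. Among the 104 pulldown calls with a position, 19 lay on chromosome 4, which carries Lepr, or 18.3% against 6.4% of genes tested (two-sided Fisher's exact test, p = 2.94e-05, adjusted p = 0.000617 over chromosomes). They included Rbm12b1 at 12.1 Mb, Snapc3 at 83.4 Mb, Acer2 at 86.9 Mb and Efcab7 at 99.8 Mb, with Lepr itself at 101.7 Mb. Chromosomes 7 and 11 passed the same Fisher's test with fewer calls, 1 of 1152 and 1 of 1248 genes tested (adjusted p = 0.0479 and 0.0325). The chromosome 4 calls included a cluster of near-identical genes between 41 and 43 Mb. Without it, 12 of 97 calls lay on chromosome 4 (Fisher's exact p = 0.0185, not adjusted over chromosomes).

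**Figure D3:**
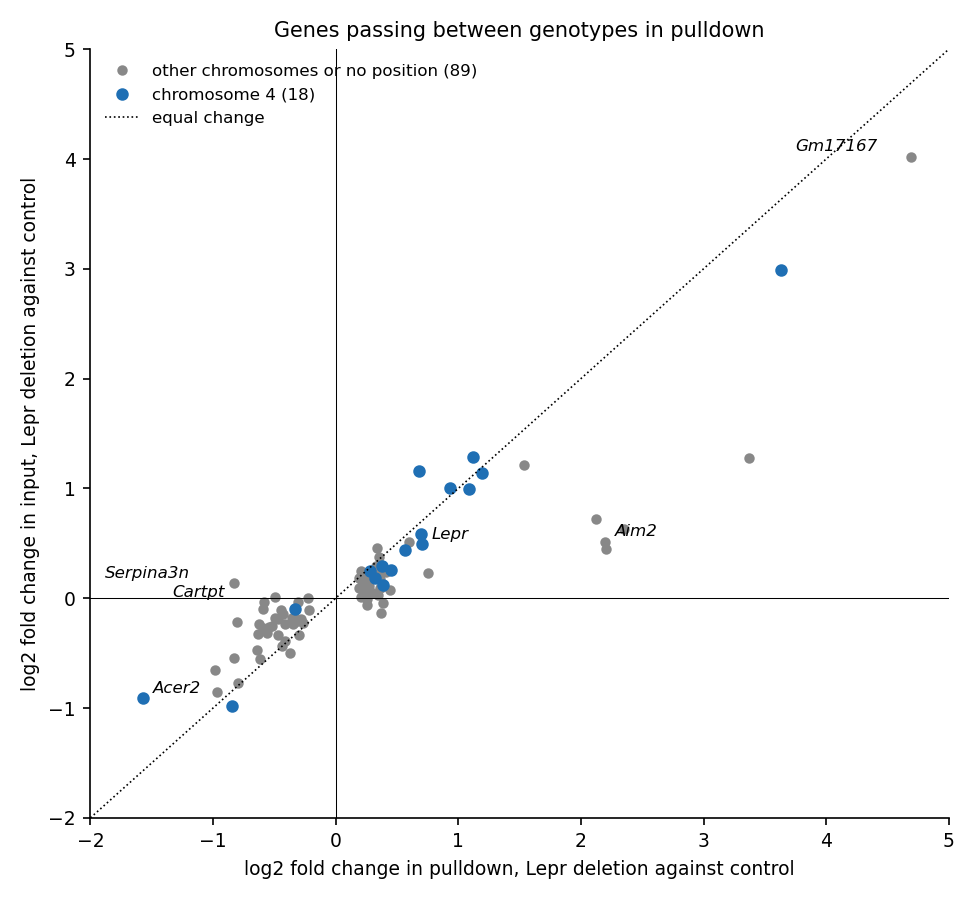
Log2 fold change of Lepr deletion against control in input (vertical) and in pulldown (horizontal) for the 107 genes passing in pulldown and tested in input, one point per gene, blue for the 18 on chromosome 4, with the dotted line marking equal change. All 18 chromosome 4 genes had the same sign in both fractions, and Cartpt and Serpina3n lay near 0 in input, with the sign of Cartpt in input turning under library totals.

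The difference of enrichment between genotypes asked which RNAs changed on ribosomes beyond their change in the whole tissue. The pulldown-to-input change of Aim2 was higher in Lepr-deletion pools, by 1.67 (SE 0.21, adjusted p = 0.00318 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and that of Serpina3n lower, by -0.98 (SE 0.15, adjusted p = 0.0391). Neither gene was enriched in pulldown in either genotype. Aim2 had 0.28 to 0.36 CPM in control pulldown against 1.8 to 2.4 in control input. In Lepr deletion it had 1.3 to 1.6 against 2.8 to 3.3 CPM, so it was depleted less there. Serpina3n differed between pulldown and input by -0.16 in mean log2 CPM in control and by -1.12 in Lepr deletion. Cartpt did not pass, at -0.56 (SE 0.09, adjusted p = 0.054), and with the pool as a block it passed, at -0.57 (adjusted p = 0.0259). Gja1 did not pass, at 0.91 (adjusted p = 0.112), although it did without pool 7 (adjusted p = 0.0115), nor did Stat3 (-0.25), Pomc (-0.42), Npy (0.37), Lepr (0.20), Leprot (-0.06), Rpl10a (-0.09) or Pnoc (-0.01, and 0.00 with RLE factors). Of 18530 genes 2 passed, and 4 with the pool as a block. Serpina3n did not pass without pool 2, 3, 5, 6, 7 or 8 (adjusted p = 0.155, 0.255, 0.055, 0.189, 0.102 and 0.106), and neither gene passed with rescaled counts. DESeq2 put Aim2 at 1.69 and Serpina3n at -0.97 (unadjusted p = 1.34e-11 and 3.3e-10) and gave neither an adjusted p. Astrocyte genes had positive values in 15 of 16 and oxidative phosphorylation genes negative values in 27 of 31, as had all 61 ribosomal protein genes (camera adjusted p = 0.000256, 2.93e-06 and 2.87e-08, and adjusted p = 0.697, 0.768 and 0.94 with an estimated correlation). Leptin-STAT3 genes had negative values in 19 of 23, among them Serpina3n (adjusted p = 0.00244, and adjusted p = 0.697 with an estimated correlation).

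The authors' deposited table held adjusted p-values for 4 of these comparisons. At the same 0.05 threshold it listed 1052 genes for pulldown between genotypes, 612 higher and 440 lower, and 329 for input, 182 higher and 147 lower. It listed 12435 genes for control enrichment and 11646 for Lepr-deletion enrichment. Of the 108 genes passing here in pulldown, 106 passed in the authors' deposited table and 2 had no value there, and of the 41 in input 35 passed and 6 had no value. Feeding peptides that did not pass here in pulldown passed in that table. They were Npy (0.419, authors' adjusted p = 0.00208), Gal (-0.446, 0.00128), Cck (-0.484, 0.00791) and Pomc (-0.339, 0.0209), while Agrp did not pass there (0.052, 0.884).

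**Figure D4:**
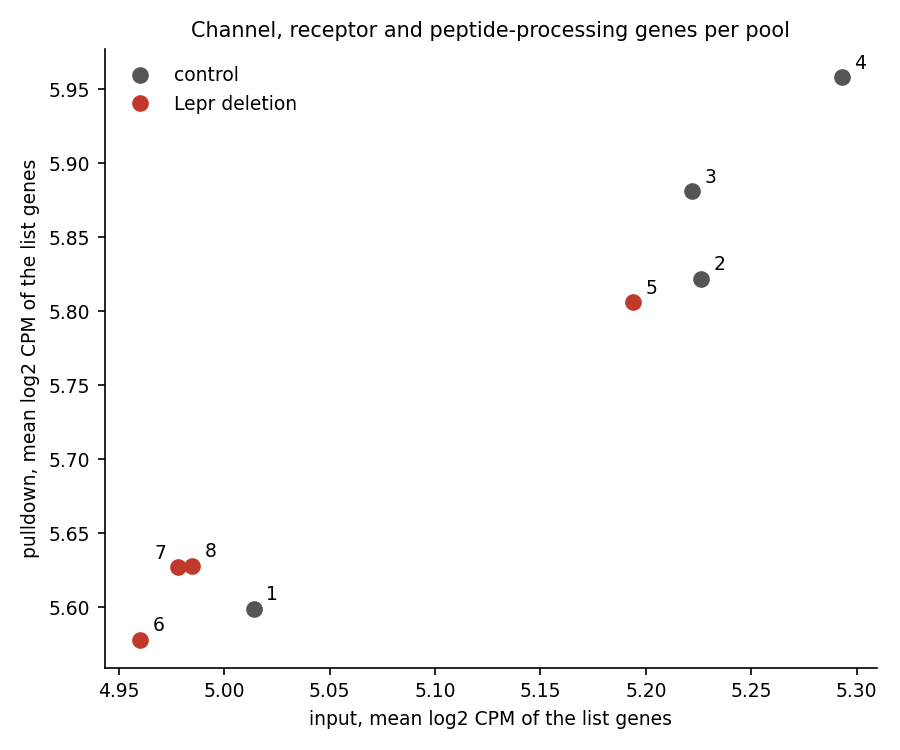
Mean log2 CPM of 104 ion channel, glutamate receptor, GABA receptor and peptide-processing genes in the pulldown (vertical) and input (horizontal) library of each of the 8 pools, numbered, grey for control and red for Lepr deletion. Control pool 1 lay near Lepr-deletion pools 6 to 8, and Lepr-deletion pool 5 near control pools 2 to 4.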

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

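The tests of explanations and the counts over other splits of the libraries in this part were chosen only after the results were seen. That of an exchange of pools 1 and 5 replaced one that counted chromosome 4 genes called over 2-fold with both pools on their label's side of the midpoint, 9 of 10 in pulldown (exact 95% interval 55.5% to 99.7%) and 5 of 7 in input (29% to 96.3%), which left input undecided. Over the whole genome the same count was a minority, with 34 of 140 genes in pulldown (17.4% to 32.2%) and 32 of 172 in input (13.1% to 25.2%). Genes with only pool 1 or only pool 5 on its label's side are left out of this count, so a low share does not show an exchange. Taken singly, pool 5 lay on its label's side in 110 and 120 of these genes and pool 1 in 50 and 59. The limits of the replacing test were chosen after counts at 0.5 and 1 log2 were seen.

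Of 18 genes called between genotypes in pulldown on chromosome 4, which carries Lepr, and tested in input, 11 also passed in input and all 18 had the same sign there. An effect confined to PNOC neurons is argued against, since the median ratio of the input to the pulldown log2 fold change was 0.83 over these 18 genes (95% bootstrap interval 0.64 to 0.937). Over 85 genes on other chromosomes the ratio was 0.535 (0.451 to 0.623), which does not mark them as confined to PNOC neurons. Both intervals came from resampling genes, not pools. Both sets were chosen for passing in pulldown, so no conclusion is drawn from the gap between their ratios. Near-identical copies fill a cluster between 41 and 43 Mb, with genes such as Gm20938 and Gm3883 (named after their values were seen). Reads shared between such copies are argued against as the whole account, since chromosome 4 stayed over-represented without the cluster. The odds ratio was then 2.15 in pulldown (Fisher's exact p = 0.0185) and 4.68 in input (p = 0.00187). Neither p was adjusted over chromosomes, so the pulldown value is weak. A genomic difference carried with the Lepr alleles on chromosome 4 stays open as an account of these calls. The odds ratios of 3.31 in pulldown and 7.79 in input (Fisher's exact p = 2.94e-05 and 8.4e-07) are part of the pattern and no test of its cause. The genes lay up to 89.6 Mb from Lepr on one side and 53.3 Mb on the other. Neither the alleles nor an effect of the deletion on these genes was tested.

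In input, mt-Nd3 was higher and Gm28438, a near-identical nuclear copy named after its values were seen, was lower in Lepr deletion, with 16390 to 20264 against 4951 to 6322 counts for mt-Nd3 and 0 to 190 against 3209 to 4237 for Gm28438. Reads moved between these copies do not account for all of it, since their summed counts still rose by 0.95 on the log2 scale (SE 0.07, adjusted p = 1.05e-05 by edgeR's quasi-likelihood test). More mitochondrial RNA in Lepr-deletion input is argued against, since the other 12 mitochondrially encoded mRNAs had a median of -0.24 (quartiles -0.29 to -0.22). A sequence difference between the mitochondrial genomes of the genotypes was not tested and stays open, and no biological explanation was tested.

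Ion channel, glutamate receptor, GABA receptor and peptide-processing genes differed between pools in both fractions, and pool 1 lay with Lepr-deletion pools 6 to 8 and pool 5 with control pools 2 to 4. An exchange of the libraries of pools 1 and 5 is argued against by chromosome 4 genes called by over 0.5 log2 without those pools, 27 in pulldown and 23 in input. Of these, 11 in pulldown and 8 in input placed both pools near their own group's mean, within 0.25 of the distance to the other's, and 0 in each fraction near the other's (lower exact 95% bounds 71.5% and 63.1% among only the genes that placed both pools near 1 group, taking linked genes as independent). Over 1 log2 these counts were 6 and 3 against 0, too few in input alone (lower bound 29.2%), while over the genome 37 genes lay near their own group and 53 near the other in pulldown at 0.5 log2 but 18 and 7 at 1 log2, and in input 22 and 32 but 12 and 8, and mt-Nd3 in input followed the labels of all 8 pools. An effect confined to PNOC neurons is argued against, since the input change was 1.06 times the pulldown change over the 4 lists. The 95% interval of 0.906 to 1.36 came from resampling genes, not pools, so it leaves out the spread between pools. That 8 of 8 pools lay on the same side of the median in input and in pulldown is part of the pattern and no test of its cause, so a difference in the animals, tissue or lysate of each pool and a genotype effect on these lists both stay open.

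Each comparison was recounted over the 35 splits of its 8 libraries or pools into groups of 4. For enrichment, 1 of 35 splits, the real one, gave as many genes in control (11381, highest other 0) and in Lepr deletion (10740, highest other 0). These splits took the libraries as exchangeable, although same-numbered input and pulldown shared a lysate. All splits but the real one mixed input and pulldown within a group. They therefore cannot decide whether chance is excluded for paired libraries. For Lepr deletion against control, 2 of 35 splits gave as many genes in pulldown (108, highest other 1935) and in input (41, highest other 1093), so chance is not excluded. In both fractions the larger count came from pool 5 with pools 2 to 4 against pool 1 with pools 6 to 8. This split differs from the real one only by exchanging pools 1 and 5. It therefore cannot tell a structure of the samples other than genotype from a genotype effect from which these pools deviate. For the difference of enrichment 2 of 35 splits gave as many genes (2, highest other 2), so chance is not excluded.

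The genotype difference of Serpina3n was lower in pulldown than in input by the test of the difference itself, at -0.98, and that of Aim2 was higher, at 1.67. The rest of this part lists single libraries far from the other 3 of their group, in CPM, and chance gives this in about 1 in 20 groups, against 26 of 564 groups here (4.6%).

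In control input, Leprot was 11.5 in pool 4 (others 8.7 to 9.03), Slc1a2 2140 in pool 4 (1820 to 1870), Rbm12b1 28.6 in pool 2 (24.3 to 25), Dner 87.7 in pool 2 (63 to 65.5), Mt2 51.7 in pool 2 (59.6 to 60.8). There, Chrm1 was 5.4 in pool 3 (6.92 to 7.07), Sst 62.4 in pool 3 (54.8 to 56.1), Gm28438 74.3 in pool 1 (57.7 to 60.1) and S100b 91.4 in pool 1 (80.3 to 81.6). In control pulldown, Rpl10a was 146 in pool 4 (others 155), Slc1a2 126 in pool 4 (111 to 113), Hspd1 399 in pool 1 (372 to 375). Rprm was 114 in pool 1 (72.4 to 76.7), Onecut3 22.2 in pool 1 (33.7 to 34.7) and mt-Nd3 0.459 in pool 1 (0 in the others). In Lepr-deletion input, Gabra4 was 23.4 in pool 6 (24.8 to 25.1), Rbfox3 139 in pool 6 (145 to 146), Flt1 6.35 in pool 7 (3 to 3.28) and Atp6v1g1 101 in pool 5 (115 to 117), and the mean of the 4 channel, receptor and peptide-processing lists was 5.19 log2 CPM in pool 5 (4.96 to 4.99). In Lepr-deletion pulldown, Erdr1 was 2.54 in pool 8 (2.41 to 2.42), Lss 25.5 in pool 8 (22.6 to 22.8). Mal2 was 92.9 in pool 5 (83.2 to 84.1), Pam 223 in pool 5 (196 to 197), Gja1 7.99 in pool 7 (4.52 to 4.98) and mt-Atp8 0.801 in pool 7 (0.422 to 0.461).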

How the results depend on the processing

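The fits without pools 1 and 5, with a Y-linked covariate, with newer dispersions and with DESeq2 on all 16 libraries were chosen only after the data were seen. Of the values of single genes followed under all alternatives, 3521 kept their side of the threshold, of which 18 that did not pass changed sign, 125 newly passed, 466 no longer passed and 6 turned.

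Lepr deletion against control in pulldown (108 genes) gave 266 with no filter, 1052 with DESeq2, 16 with rescaled counts, 41 and 20 with limma on log2(TPM + 1) and log2(TPM + 0.1). It gave 648 at an adjusted p of 0.1, 508 with all 16 libraries in one fit, 24 with a glial covariate, 29 with a Y-linked covariate, 1383 with DESeq2 on all 16 libraries and 3363 without pools 1 and 5. Leaving out each library gave 19 to 1262, the lowest without pool 6 or 7 and the highest without pool 5. The same contrast in input (41 genes) gave 108 with library totals, 261 with no filter, 369 with DESeq2, 11 with rescaled counts, 18 and 17 with limma on log2(TPM + 1) and log2(TPM + 0.1). It gave 106 at an adjusted p of 0.1, 246 with a Y-linked covariate, 287 with DESeq2 on all 16 libraries and 1957 without pools 1 and 5. Leaving out each library gave 19, without pool 3, to 402, without pool 1. The count at 0.1 rose by construction, and the cause was not tested for the others. On the simulated counts DESeq2 made 39 false among 204 calls in pulldown, against 13 among 167 for edgeR. In input it made 29 among 177, against 12 among 152 for edgeR.

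Pulldown against input gave 2523 genes in control and 2355 in Lepr deletion against a 2-fold change, a stricter test by construction, and 10812 to 11613 and 10095 to 10753 with each library left out. The difference of enrichment (2 genes) gave 4 with RLE factors, 4 with library totals and 6 with no filter. With DESeq2 it gave 20, with 0 shared because DESeq2 gave neither Aim2 nor Serpina3n an adjusted p. With rescaled counts it gave 0 (edgeR, 1736 at an unadjusted p under 0.05). It gave 6 and 5 with limma on log2(TPM + 1) and log2(TPM + 0.1), 4 at an adjusted p of 0.1, 4 with the pool as a block, 87 without pools 1 and 5, and 1 to 3 with each pool left out, with 1 without pool 2, 5 or 6. With the pool as a block Cartpt passed (adjusted p = 0.0259), and the block changed the call of no other named gene. The cause was not tested.

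Gene lists passing camera went from 9 to 0 in pulldown between genotypes, 13 to 0 in input, 18 to 3 and 21 to 0 for enrichment in control and Lepr deletion, and 4 to 0 for the difference of enrichment with an estimated correlation. With fry 0, 0 and 1 passed in the genotype comparisons and the difference of enrichment, and 26 and 22 for enrichment in control and Lepr deletion. Leprot turned from -0.34 in control to 0.21 with library totals and 0.60 and 0.66 with log2(TPM + 1) and log2(TPM + 0.1), and from -0.39 in Lepr deletion to 0.065, 0.45 and 0.49, where these scalings moved the median of all genes by 0.455 to 0.975. The other causes were not tested. At 4 pools a group the simulated 1.25-fold changes were mostly missed, so small differences that did not pass are not shown to be absent.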

Other observations

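The counts below without pools 1 and 5 were chosen only after the data were seen.

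Without those pools, 3363 of 16918 genes passed between genotypes in pulldown and 1957 of 17838 in input, and no set test was run on these fits. In pulldown, ER stress genes fell in 9 of 20 and rose in 0, cholesterol synthesis genes fell in 8 of 19 and rose in 1, and metabolic receptor genes fell in 10 of 37 and rose in 4. Feeding peptides fell in 14 of 34 and rose in 2, immediate early genes went both ways (7 of 22 fell and 5 rose), and heat shock genes rose in 12 of 14 and fell in 0. In input without those pools, heat shock genes rose in 10 of 14, nuclear oxidative phosphorylation genes in 9 of 31 and ribosomal protein genes in 13 of 61, with 0 falling in each. Mitochondrially encoded mRNAs fell in 11 of 13 and rose in 1 there, and metabolic receptor genes fell in 9 of 37 and feeding peptides in 7 of 34, with 0 rising in both. The edgeR test behind these counts left 3 pools a group, and pools 1 and 5 were left out because of values measured in them, so the counts are not independent evidence of a genotype effect.

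Heat shock genes had mean levels of 7.28 to 7.50 log2 CPM in the Lepr-deletion pulldown libraries and 7.07 to 7.27 in the control ones.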
